A study of Mus musculus with 8 samples.

How the data were processed

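Tumors were homogenized, RNA was extracted with TRIzol, and libraries of poly-A RNA were made without strand information, per the labels' protocols, so that reads of a gene and of an overlapping antisense gene were not told apart. The deposited expression values are log2(TPM + 1), per the values themselves, which return to TPM with 2 decimals; TPM came from RSEM on build mm39, per the submitters' processing notes, and the aligner, versions and annotation release are not given in the sources used here. Near-identical copies, such as the mitochondrial-like gene models, may share reads in such estimates and are uncertain. The receptor measures were made by the authors with MiXCR, per the labels, as numbers of clonotypes and clones, entropy, clonality and isotype shares, with no stated scaling to depth; isotype shares carry a tiny constant that was rounded away. The authors' deposited comparison comes from DESeq2, which the submitters' processing notes name, with, per the file headers, a mean normalized signal per gene, a log2 fold change, a Wald score and p-values, of which the log2 values and adjusted p were used; which libraries entered it and how the authors treated portions is not given in the sources used here, and its direction was read from the sign of Colq. Its IDs were matched to symbols for 26581 genes (96.1%).

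Groups and replicate numbers came from the sample titles: 3 Colq tumors with 1 library each, and 3 vector tumors, 2 of them as 2 portions. Portions were averaged before any test, on the log2 scale for the main fit. They were averaged as TPM for size factors, TPM means and shares of TPM, and as deposited values for receptor measures. Genes with a mean TPM of at least 1 over the 6 tumors were tested on log2(TPM + 1) with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with trend), with Benjamini-Hochberg adjustment. Fold changes are Colq minus vector. The 48 gene lists held 903 distinct genes, of which 885 were in the table and 704 were tested; lists of at least 5 tested genes entered camera with a preset correlation of 0.01, and camera with an estimated correlation and fry were run beside it. Single values were compared by an exact two-sided permutation test over tumors, whose smallest p is 0.1. Receptor measures were processed in Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9. The authors' deposited comparison was set beside the fold changes and calls computed here, by correlation across genes and by counts of shared calls, with no test of its own.

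Named genes followed a rule set, like the lists and tests, before the data were examined: Colq and Ache; the 15 higher and 15 lower genes with the largest absolute log2 fold change among those called whose groups did not overlap, passing over numbered gene models; up to 4 members of each described list, by smallest p; and the 5 genes of smallest adjusted p per direction in the authors' table. On simulated data for 13726 genes with 200 changed, the tumor-level fit recovered 73% of genes changed by a log2 fold of 1 and 98% of those changed by 2, with 7 false calls, and found the 1 list that was moved and 0 others. The simulated genes varied independently of one another, and far fewer changed than were called in the real data. Genes of a real list may vary together, so the 0 other lists do not measure false list calls here.

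Other settings chosen then were pseudocounts of 0.1 and 0.5, no filter and a mean TPM of at least 5, size factors, quantile normalization, TPM rescaled without mitochondrial, immunoglobulin and haemoglobin genes, other treatments of the portions, a replicate block, robust eBayes, and leaving out each tumor. Added after the data were seen were a loess removal (span 0.5) of the trend on exonic length and GC content, taken from a GRCm38 annotation that differs from the authors' build and covering 96.2% of tested genes; the 3 Colq libraries averaged and counted as 1 sample, which is assumed to vary like the vector tumors, the only source of spread in that fit; and genes of at least 2000 bases only. TPM keeps no depth, so precision rests on the spread between tumors.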

Results

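Subcutaneous tumors of the mouse melanoma line B16 carrying a gp100 antigen (B16-mhgp100) were grown in C57BL/6 mice, either with over-expression of Colq or with the vector alone. Colq encodes the collagen-like tail that anchors acetylcholinesterase to the basement membrane of the neuromuscular junction. All mice received an antibody against PD-1, a checkpoint receptor of T cells, at 200 µg per dose for 4 doses, 2 per week, from day 10 after inoculation, and tumors were taken 1 day after the last dose. The data are RNA-seq of polyadenylated RNA from bulk tumors, held as TPM for 28918 genes in 8 libraries, with a table of T cell and B cell receptor measures for the same libraries. The 3 Colq tumors gave 3 libraries, and the 3 vector tumors gave 5, because 2 of them were sequenced as 2 portions each. Portions of a tumor were averaged, so that each comparison set 3 tumors against 3. An SD over vector tumors therefore leaves out the spread between portions. TPM keeps no library depth, so the depth behind each value is unknown; each library held between 19887 and 21602 genes above 0.

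The over-expressed gene was examined first, as a check of the labels. Colq (ENSMUSG00000057606; chromosome 14, 31523082 to 31591343, minus strand, in the GRCm38 annotation) stood at 4.31 ± 0.63 TPM (SD, n = 3) in Colq tumors and at 0.122 ± 0.058 TPM (SD, n = 3) in vector tumors. The libraries of the Colq group held 4.05, 5.03 and 3.86 TPM, and those of the vector group between 0 and 0.24 TPM. These values do not tell over-expressed Colq from Colq of host tissue. Skeletal muscle genes rose in the same tumors, with a median log2 fold change of 2.88, which limits the check. The log2 fold change on the log2(TPM + 1) scale, which understates the change of low genes, was 2.24 (SE 0.16; limma, adjusted p = 2.8e-05). An exact two-sided permutation test over the 6 tumors gave p = 0.1, the smallest that 3 against 3 allows. Ache, which encodes the acetylcholinesterase that the Colq tail anchors, stood at 0.47 ± 0.03 TPM in Colq tumors and 0.77 ± 0.38 TPM in vector tumors (SD, n = 3 each), under the expression filter, with an exact permutation p of 0.4.

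**Figure D1:**
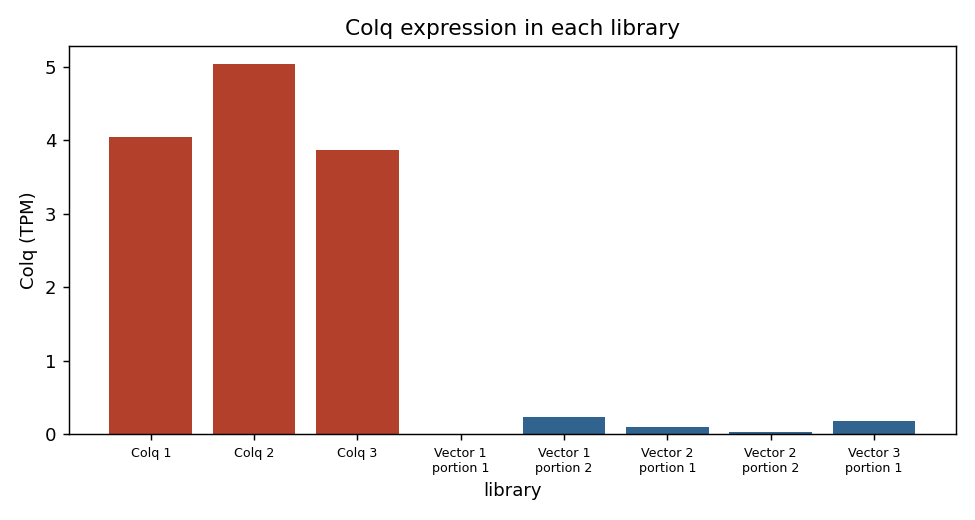
Colq in TPM (bars; vertical axis, from 0) in each of the 8 libraries (horizontal axis; red, Colq tumors; blue, vector tumors, with portions of a tumor named). The 3 Colq libraries lie between 3.86 and 5.03 TPM, and the vector libraries between 0 and 0.24 TPM.

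The comparison of Colq with vector tumors asked which transcripts differ after the same antibody treatment. Among the genes with the largest rises were Retnla, a secreted product of alternatively activated macrophages, at 232.5 ± 4.74 TPM against 4.84 ± 1.26 TPM, and Saa3, an acute phase protein, at 554.8 ± 16.7 against 36.7 ± 25.4 TPM (SD, n = 3 each). The same group held the skeletal muscle genes Pvalb, Tnnc2, Tnni2, Myl1 and Tnnt3, with log2 fold changes between 3.67 and 4.43. It also held the matrix genes Dpt (3.92) and Clec3b (3.86), the peptide hormone gene Cck (4.14) and the heart and muscle isoform Cox8b of a cytochrome oxidase subunit (3.70). The immunoglobulin kappa constant gene Igkc (3.93) rose too, as did the noncoding RNAs Bc1 (5.37, SE 1.54, adjusted p = 0.016) and Snora73b (3.84). Bc1 varied widely, at 198.2 ± 158 TPM in Colq tumors, and its call was lost without Colq replicate 3 (adjusted p = 0.061), without Vector replicate 1 (0.066) and without Vector replicate 2 (0.060). The call was also lost with no filter (0.052), with robust moderation (0.059), with the length and GC trend removed (0.066) and with the Colq libraries as 1 sample (0.16), a fit with fewer samples in which the vector tumors supply all of the spread. A variable segment of the kappa light chain, among the largest rises, stood at 28.0, 26.3 and 25.7 TPM in the Colq libraries and at 0 in every vector library. The lower genes in Colq tumors included Cntn6, a neural adhesion protein, at 0.12 ± 0.056 against 12.6 ± 8.58 TPM. The cartilage matrix gene Matn3 (log2 fold change -2.95) and Capn6 (-2.77) followed, with the basement membrane collagens Col4a1 (-2.34) and Col4a2 (-2.23). Further genes were Papln (-2.30), Igsf3 (-2.27), Crmp1 (-2.24), Syne2 (-2.19) and Akap12 (-2.16). The last of this group were the actin bundling gene Fscn1 (-2.15), Fndc3c1 (-2.14), the endothelial cadherin Cdh5 (-2.11), Fat1 (-2.09) and the spliceosome component Prpf8 (-2.08).

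Of 13726 genes tested, 1556 were higher and 8181 lower in Colq tumors (limma, Benjamini-Hochberg adjusted p under 0.05), so that 16.0% of the calls were higher. The 3 tumors of one group lay apart from the 3 of the other for 74.7% of tested genes, where chance gives 10%. These numbers depend on the scale. The median log2 fold change of all tested genes was -0.50, and after median-of-ratios size factors, which set that median near 0, 3843 genes were higher and 3505 lower, a share of 52.3% higher. All 3505 of the latter were also among the 8181, and 471 genes that were lower as deposited were higher after size factors. A fold change is therefore read against the median of -0.50. Size factors were applied to portions averaged as TPM, an averaging that by itself gave 1507 genes higher and 8204 lower.

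Fold changes followed exonic length. The 356 tested genes under 500 bases had a median log2 fold change of 0.50, those from 2000 to 4000 bases -0.38, and the 2172 genes of 8000 bases or more -0.88. Mitochondrially encoded genes took 7.77 ± 0.35% of TPM in Colq tumors and 4.50 ± 0.67% in vector tumors, and ribosomal protein genes 20.6 ± 0.47% and 14.0 ± 0.67% (SD, n = 3 each; exact permutation p = 0.1 for each, the smallest possible). With the trend on length and GC content removed, an alternative chosen after the data were seen, 2930 genes were higher and 3090 lower among the 13211 with a length, and 1297 and 2938 of these shared their direction with the calls on deposited TPM. The removal also brought the median log2 fold change to -0.022, so changes against deposited TPM mix centering with length.

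**Figure D2:**
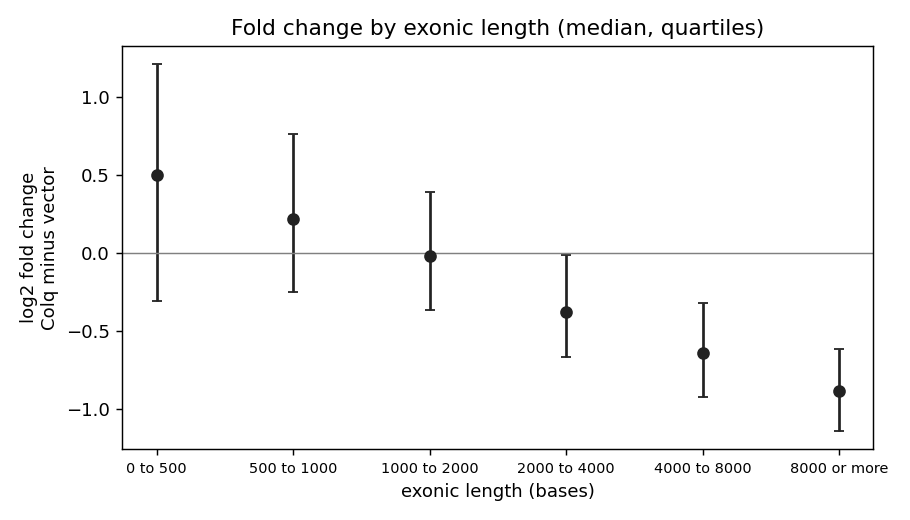
Log2 fold change, Colq minus vector (vertical axis), of tested genes grouped by exonic length in bases (horizontal axis). Points are medians and bars the quartiles. The median falls from 0.50 under 500 bases to -0.88 at 8000 bases or more.

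Gene lists fixed before the data were examined were then compared, 46 of 48 having at least 5 tested genes. By camera with its preset correlation of 0.01, 27 lists passed an adjusted p of 0.05, 20 toward higher and 7 toward lower in Colq tumors relative to other genes. With an estimated correlation 0 passed by camera, where 7 had an unadjusted p under 0.05. By fry, which tests a list by itself and against 0, 30 passed. The median of all tested genes, -0.50, can carry a list past that test. Hypoxia genes passed by fry only (adjusted p = 0.00060). Passing camera at the preset correlation but not fry were macrophage (fry adjusted p = 0.11), pan T cell (0.16), skin (0.17), complement (0.17) and neutrophil (0.075) genes. So did classical activation (0.062), fibroblast (0.32), exhaustion (0.32), MHC class II (0.55) and immunosuppressive (0.90) genes. The other ways of dividing the 6 tumors into 3 and 3 gave between 12 and 28 lists, so the count of lists alone does not set the real grouping apart. Counts of members called are therefore given, with both p-values. These counts are taken against 0, and over all 13726 tested genes 1556 rose and 8181 fell as deposited. After size factors 3843 rose and 3505 fell. A majority of lower members as deposited therefore does not by itself set a list apart from other genes. Counts adjusted over the list alone were the same as those over all genes for the lists described, except where another count is given. An adjusted p is that on deposited TPM unless another scale stands beside it.

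Skeletal muscle showed the largest median. Of its 22 tested genes 20 rose and 0 fell, with a median log2 fold change of 2.88 (adjusted p = 2.6e-21; adjusted p = 0.20 with an estimated correlation). The median was 3.22 after size factors and 2.95 with the length trend removed. Pvalb, a calcium buffer of fast fibers, was at 52.4 ± 1.71 against 1.87 ± 0.34 TPM, Ckm, the muscle creatine kinase, at 124.5 ± 3.32 against 10.0 ± 2.79, and Myoz1 at 10.6 ± 0.25 against 0.557 ± 0.047. Portions of a vector tumor differed more than these SDs show. Pvalb stood at 0.59 and 3.00 TPM in vector tumor 1 and at 4.46 and 0 in vector tumor 2, while every Colq library held at least 50.8. Keratinocyte and skin genes rose in 8 and fell in 2 of 14 (median 1.09; adjusted p = 3.2e-05; adjusted p = 0.47 with an estimated correlation), and the list did not pass after size factors (adjusted p = 0.14). Krt15 was at 6.76 ± 0.95 against 0.292 ± 0.36 TPM, while Lgals7 fell by 0.73 on the log2 scale, a call lost after size factors (-0.17, adjusted p = 0.26). The skin counts rest on single portions: 1 rose and 2 fell with first portions (median 0.33), 12 rose and 1 fell with second portions (median 1.96), and 3 rose and 2 fell with portions averaged as TPM. Size factors were applied after that last averaging, so for skin genes the effects of averaging and scale are not told apart. Counting the Colq libraries as 1 sample, 1 rose and 1 fell. In the first portion of vector tumor 1 Lor stood at 10.6 and Krt10 at 15.5 TPM, above the 8.63 and 13.7 TPM of the highest Colq library, while in the other vector libraries neither exceeded 0.62 TPM. Leaving out single tumors gave between 4 rises, without Colq replicate 2 and without Vector replicate 2, and 10 rises, without Vector replicate 1. Among 25 fibroblast genes 12 rose and 9 fell (adjusted p = 0.00021; adjusted p = 0.47 with an estimated correlation; 0.067 after size factors). With the length trend removed 15 rose and 3 fell, and the median moved from 0.35 to 0.96 (adjusted p = 0.00046), against 0.64 after size factors. The list had Dpt and Clec3b higher and the matrix genes Fbln1 (-1.19) and Col6a3 (-1.18) lower, the last no longer called with the length trend removed (-0.14, adjusted p = 0.33).

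Macrophage and monocyte transcripts were among the higher groups, in the same tumors in which muscle genes had a median of 2.88. Of 20 macrophage genes 6 rose and 2 fell on deposited TPM, 5 and 2 adjusted over the list alone (adjusted p = 5.4e-06; adjusted p = 0.47 with an estimated correlation). After size factors 16 rose and 1 fell. As deposited 12 rose and 2 fell without Vector replicate 2 (median 0.80), and 6 rose and 5 fell without Vector replicate 3 (median 0.25). Lyz2, the myeloid lysozyme, was at 869.3 ± 4.37 against 187.5 ± 32.5 TPM, Marco at 4.81 ± 0.37 against 0.782 ± 0.41, and Mrc1, the mannose receptor, at 15.1 ± 0.66 against 8.88 ± 1.33. In the list of alternative activation 10 of 16 rose and 5 fell (adjusted p = 1.3e-06; adjusted p = 0.20 with an estimated correlation), with Cd209f at 36.4 ± 1.74 against 3.32 ± 0.75 TPM and Arg1, arginase, at 32.9 ± 1.24 against 13.4 ± 1.59. In that of classical activation 6 of 10 rose and 2 fell (adjusted p = 0.00043; adjusted p = 0.43 with an estimated correlation). Its members Cd40 (1.27) and Cd86 (1.49), both costimulatory, and Il1b (0.89) rose, and Cxcl10, a chemokine induced by interferon, fell by 0.43 as deposited but stood at 0.14 after size factors (adjusted p = 0.070). Monocyte genes rose in 5 and fell in 2 of 10 (adjusted p = 0.00084; adjusted p = 0.43 with an estimated correlation; 0.051 after size factors; 3 rises without Vector replicate 1, without Vector replicate 3, without Colq replicate 1 and without Colq replicate 2), with Plac8 at 2.91, F13a1 at 1.77, Ccr2 at 1.03 and the matrix gene Fn1 at -1.57. Chemokine genes rose in 19 and fell in 5 of 27 (adjusted p = 5.1e-12; adjusted p = 0.20 with an estimated correlation): Ccl6 reached 344.9 ± 3.23 against 35.8 ± 5.32 TPM, Ccl8 880.2 ± 31.2 against 122.8 ± 28.7, and the eosinophil attractant Ccl11 18.3 ± 1.65 against 2.78 ± 0.75.

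Conventional dendritic cell genes rose in 10 and fell in 2 of 13 (adjusted p = 5.7e-06; adjusted p = 0.20 with an estimated correlation), with Clec10a at 2.44 and Cd209a at 1.62, and Fscn1 at -2.15 and Sirpa at -0.83 on the lower side. The call of Sirpa was lost with the length trend removed (-0.15, adjusted p = 0.17). Neutrophil genes rose in 4 and fell in 1 of 11 (adjusted p = 0.00015; adjusted p = 0.39 with an estimated correlation), led by Clec4d (1.30) and Retnlg (2.01). Its median was 0.89 on averaged portions, 0.12 with first portions (3 rises), 1.57 with second portions (7 rises), 1.38 without Vector replicate 1 and 0.31 without Vector replicate 3. Mast cell and eosinophil genes rose in 5 and fell in 1 of 6 (adjusted p = 0.00019; adjusted p = 0.20 with an estimated correlation): Ear2 (2.67), Cma1 (1.96) and Mcpt4 (1.66) rose, and Kit, which melanocytes also express, fell by 1.56 on the log2 scale, a call lost with the length trend removed (-0.71, adjusted p = 0.059) and with the Colq libraries as 1 sample (adjusted p = 0.053). Complement genes rose in 5 and fell in 3 of 16 (adjusted p = 0.00015; adjusted p = 0.47 with an estimated correlation), with Cd55 at 2.06 and Cfp at 1.42 and with C2 at -0.91. After size factors 11 complement genes rose and 2 fell, and as deposited 8 rose and 2 fell without Vector replicate 2, and the median moved from 0.39 to 0.17 without Vector replicate 3. Plasmacytoid dendritic cell genes had 1 higher and 1 lower of 6 and did not pass (adjusted p = 0.34), with a median of -0.23, a mean of 0.14 and a median of 0.21 after size factors. Tcf4 fell by 1.34, a call lost with the length trend removed (-0.25, adjusted p = 0.071), and Cox6a2, also a muscle gene, rose by 2.12. Bst2 stood at -0.14 as deposited (adjusted p = 0.12). It passed toward higher after size factors (0.43, adjusted p = 0.0015), and toward lower with quantile normalization (-0.28, adjusted p = 0.043), with the length trend removed (-0.30, adjusted p = 0.036) and without Vector replicate 1 (-0.22, adjusted p = 0.0078).

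T cell transcripts were higher in part, again in the tumors with the higher muscle genes. Of 15 CD8 T cell and cytotoxic effector genes 11 rose and 0 fell (median 0.91; adjusted p = 3.2e-09; adjusted p = 0.39 with an estimated correlation). After size factors 15 rose, and 8 rose with the length trend removed. As deposited 7 rose without Colq replicate 3. Nkg7, a cytotoxic granule protein, was at 16.7 ± 2.83 against 5.81 ± 1.00 TPM, the activating receptor gene Klrk1 at 13.6 ± 1.54 against 4.10 ± 1.37, and Ifng, interferon gamma, at 2.84 ± 0.19 against 1.28 ± 0.084. Pan T cell genes rose in 6 and fell in 2 of 17, 5 and 2 adjusted over the list alone (adjusted p = 0.00015; adjusted p = 0.42 with an estimated correlation), against 9 and 0 after size factors and 9 and 1 with the length trend removed, with Trbc1 at 1.38, Cd3d at 1.53 and Tcf7, a transcription factor of naive and memory T cells, at -0.84. The median of the list was 0.29, and 0.10 without Vector replicate 3. The call of Tcf7 was lost after size factors (-0.31, adjusted p = 0.060) and with quantile normalization (-0.28, adjusted p = 0.081). Tcf7 stood at 16.4 TPM in vector tumors, against 1.06 for Cd3d and 3.20 for Trbc1. The source of Tcf7 in bulk tissue need not be T cells. The list of exhaustion and checkpoint genes had 1 higher and 2 lower of 15, with a median of 0.06 and a mean of -0.14 (adjusted p = 0.040; adjusted p = 0.51 with an estimated correlation; 0.21 after size factors; 0.34 with the length trend removed). It had 5 higher and 2 lower with a median of 0.47 after size factors, and 3 and 2 with a median of 0.24 with the length trend removed. The list also did not pass with quantile normalization (0.20), at a mean TPM of at least 5 (0.23), with all 8 libraries as independent (0.093), with tumor as a random block (0.095), with first portions (0.11), without Colq replicate 3 (0.064; median -0.060) or without Vector replicate 3 (0.25; median -0.085). Nr4a3 fell by 2.08 and Nr4a1 by 1.27, Tnfrsf9 rose by 0.33, a call lost with first portions (adjusted p = 0.11) and with the Colq libraries as 1 sample (0.16), and Pdcd1, which encodes PD-1, was at 0.62 (adjusted p = 0.081), passing after size factors (0.017), with quantile normalization (0.034), with the length trend removed (0.039) and without Vector replicate 2 (0.048). In vector tumors Nr4a1 stood at 86.8 and Nr4a3 at 48.3 TPM, so the source of these 2 genes need not be T cells either. CD4 helper and regulatory genes had 1 higher and 0 lower of 7, and 0 and 0 adjusted over the list alone (limma), and the list did not pass (adjusted p = 0.18). Its median was -0.18 as deposited and 0.23 after size factors, and its mean 0.01. The higher gene was Il10 (0.84), whose call was lost without Colq replicate 1 (adjusted p = 0.064), without Colq replicate 3 (0.062), with first portions (0.13), with the length trend removed (0.065) and with the Colq libraries as 1 sample (0.083). Ikzf2 (-0.43) and Bcl6 (-0.35) did not pass and changed sign with the length trend removed, Bcl6 also after size factors. Ikzf2 passed without Colq replicate 3 (-0.57, adjusted p = 0.043) and Bcl6 without Vector replicate 3 (-0.45, adjusted p = 0.039). Naive and central memory genes did not pass (2 higher and 3 lower of 7; median 0.056, mean -0.11; adjusted p = 0.16), and had 4 higher and 1 lower both after size factors (median 0.45) and with the length trend removed (median 0.60), with Foxp1 (-1.03) lower and Ccr7 (0.96) higher. The call of Foxp1 was lost with the length trend removed (-0.087, adjusted p = 0.46). The NK cell list had 3 tested genes, all shared with the cytotoxic list, Klrk1 (1.56), Xcl1 (1.09) and Gzma (1.69), each higher on deposited TPM. The call of Xcl1 was lost with the length trend removed (0.50, adjusted p = 0.13) and with second portions (0.82, adjusted p = 0.065), and those of Xcl1 and Gzma with the Colq libraries as 1 sample (adjusted p = 0.053 and 0.11).

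Plasma cell genes had 3 higher and 3 lower of 6 on deposited TPM, and 3 higher and 0 lower both after size factors and with the length trend removed (adjusted p = 0.037; adjusted p = 0.39 with an estimated correlation; 0.16 after size factors). The median was 1.08, and -0.45 over the 5 members tested after mitochondrial, immunoglobulin and haemoglobin genes were left out and TPM was rescaled. The list did not pass without Vector replicate 1 (adjusted p = 0.053), without Vector replicate 3 (0.063), with pseudocount 0.1 (0.053), with quantile normalization (0.18), without mitochondrial, immunoglobulin and haemoglobin genes (0.64) or with the length trend removed (0.13). The higher members were the antibody genes Jchain, at 6.02 ± 0.43 against 0.087 ± 0.12 TPM, Igkc, at 48.5 ± 1.82 against 3.04 ± 3.01, and Ighm, at 37.2 ± 2.40 against 5.85 ± 4.02. Xbp1, a secretory regulator used by many cells, was lower (-0.50) as deposited and at 0.075 after size factors. B cell genes had 3 tested members, Blnk (0.28), Cd79b (0.14) and Cd22 (0.05), none past the threshold. With no filter the B cell list had 2 higher and 0 lower of 18 and passed toward higher (adjusted p = 0.0074), and the NK cell list had 9 higher and 1 lower of 13 and passed too (adjusted p = 4.7e-06). Cd79b and Cd22 changed sign when single tumors were left out: Cd79b was at -0.073 without Colq replicate 2, -0.0028 without Vector replicate 1 and -0.012 without Vector replicate 3, and Cd22 at -0.21 without Colq replicate 1 and -0.13 without Vector replicate 3. Blnk passed with the length trend removed (0.90, adjusted p = 0.029) and without Vector replicate 2 (0.57, adjusted p = 0.037).

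Interferon and antigen presentation lists depended on the scale. The median of the interferon gamma list was -0.24 as deposited and 0.33 after size factors, and those of the type I interferon list -0.41 and 0.15. Of 28 interferon gamma response genes 4 rose and 13 fell as deposited, 4 and 12 adjusted over the list alone, and 15 rose and 3 fell after size factors. The list passed on the second scale (adjusted p = 0.017) and not on the first (adjusted p = 0.22), where it passed without Vector replicate 2 (9 higher and 10 lower, adjusted p = 0.0497). Nlrc5 (-1.06) and Gbp7 (-0.96) were lower on both scales, and Nlrc5 was no longer called with the length trend removed (-0.17, adjusted p = 0.086). In the type I interferon list 2 rose and 10 fell of 28 as deposited (adjusted p = 0.38), 2 and 22 without Vector replicate 3, and 5 rose and 2 fell after size factors. The list held Ifi27l2a at 341.8 ± 4.75 against 55.7 ± 18.7 TPM, Ifih1 at -1.14 and Rsad2 at -1.34; Irf9 was at -0.43 as deposited and 0.14 after size factors. MHC class I genes rose in 4 and fell in 11 of 21 (adjusted p = 0.55), and in 10 and 6 after size factors, with Calr (-0.91), H2-Q4 (-0.92) and Tapbp (-0.96) lower on both scales. MHC class II genes rose in 4 and fell in 2 of 11, 3 and 2 adjusted over the list alone (adjusted p = 0.0085; adjusted p = 0.47 with an estimated correlation; 0.096 with the length trend removed; 0.083 with quantile normalization). After size factors 8 rose and 0 fell. As deposited 2 rose and 3 fell with first portions, and the median moved from 0.36 to 0.59 without Vector replicate 2 and to 0.19 without Vector replicate 3. H2-Ab1 was at 318.7 ± 5.42 against 207.8 ± 56.9 TPM, a call lost with first portions (adjusted p = 0.052) and with the Colq libraries as 1 sample (0.15), and Ifi30 at -0.48 as deposited and 0.10 after size factors. Immunosuppressive ligands and enzymes had 8 higher and 8 lower of 20 on deposited TPM, and 9 higher and 3 lower both after size factors and with the length trend removed (adjusted p = 0.0059; adjusted p = 0.51 with an estimated correlation; 0.14 after size factors; 0.098 at a mean TPM of at least 5; 0.078 with quantile normalization). The median was 0.20, and -0.074 without Vector replicate 3, with Arg1 higher and Tgfb3 (-1.49), Pvr (-0.75) and Cd276 (-1.29) lower. The call of Pvr was lost after size factors (-0.19, adjusted p = 0.081) and with the length trend removed (-0.058, adjusted p = 0.58).

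The lists that passed toward lower in Colq tumors were those of cell cycle, MYC targets, glycolysis, cholesterol synthesis, unfolded protein response, endothelial cells and basement membrane. In the same comparison all tested genes of 8000 bases or more had a median of -0.88. Of 17 basement membrane genes 15 fell and 0 rose, and 14 fell after size factors (median -1.56; adjusted p = 0.0014; adjusted p = 0.39 with an estimated correlation). With the length trend removed 10 fell and 2 rose, and the median was -0.62, against -0.99 after size factors. Col4a1 was at 18.1 ± 1.62 against 95.7 ± 5.16 TPM, and Hspg2, the perlecan to which the Colq tail binds, at 10.7 ± 0.82 against 42.7 ± 1.79. Endothelial genes fell in 18 of 22, and in 12 after size factors (adjusted p = 0.042; adjusted p = 0.61 with an estimated correlation). The endothelial list did not pass with second portions (adjusted p = 0.051), without Colq replicate 1 (0.054), without Vector replicate 1 (0.092), with the Colq libraries as 1 sample (0.051) or at a mean TPM of at least 5 (0.18). Its median was -1.08, -0.64 after size factors, and -0.50 with 11 lower once the length trend was removed. Eng was at -1.39, Kdr, a receptor of VEGF, at -1.64 and Cdh5 at -2.11. Cell cycle genes fell in 31 and rose in 1 of 35, against 17 and 9 after size factors (adjusted p = 0.0034; adjusted p = 0.47 with an estimated correlation), with Top2a at -1.43 and Mcm4 at -1.54. MYC targets and ribosome biogenesis genes fell in 22 of 23, against 13 after size factors, with 4 then higher (adjusted p = 0.00033; adjusted p = 0.43 with an estimated correlation); Myc itself was at 55.3 ± 1.22 against 152.4 ± 7.34 TPM. Cholesterol synthesis genes fell in 21 of 21, against 16 with 1 higher after size factors (adjusted p = 0.0011; adjusted p = 0.48 with an estimated correlation), including Cyp51 (-1.13). Glycolysis genes fell in 17 of 19, against 11 with 3 higher after size factors (adjusted p = 0.0014; adjusted p = 0.39 with an estimated correlation), including Slc16a3 (-1.37), a lactate transporter, and Hk1 (-1.63). Unfolded protein response genes fell in 22 of 25, against 11 with 3 higher after size factors, where the list did not pass (adjusted p = 0.0096, 0.076 after size factors, and 0.057 at a mean TPM of at least 5; adjusted p = 0.51 with an estimated correlation), including Pdia6 (-0.98) and Hsp90b1 (-1.08). With the length trend removed the medians of the cell cycle, MYC target, cholesterol, glycolysis and unfolded protein response lists were -0.40, -0.44, -0.46, -0.25 and -0.52, against -0.78, -0.97, -1.03, -0.84 and -0.81 as deposited. After size factors, which center the median gene without removing length, they were -0.22, -0.40, -0.45, -0.26 and -0.25. The shrinkage from deposited TPM therefore does not measure an effect of length.

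The remaining described lists were those of respiration, pigment and the synapse. All 13 mitochondrially encoded genes rose (adjusted p = 2.4e-12; adjusted p = 0.25 with an estimated correlation), led by mt-Nd3 at 2.15, but 5 rose and 1 fell with the length trend removed, where the list did not pass (adjusted p = 0.060). Oxidative phosphorylation genes divided into 10 higher and 10 lower of 25, 11 and 10 adjusted over the list alone (adjusted p = 0.00033; adjusted p = 0.20 with an estimated correlation; 0.059 with quantile normalization), against 19 and 2 after size factors and 13 and 2 with the length trend removed, with Ndufa4 (1.14) and Cox7a2 (1.10) higher and Cs, citrate synthase, at -0.97. Melanocyte and pigment genes fell in 15 and rose in 2 of 23, against 9 and 7 after size factors and 9 and 6 with the length trend removed, and did not pass (adjusted p = 0.68). The list passed toward lower with quantile normalization (2 higher and 12 lower, adjusted p = 0.010). Sox10 was at 150.6 ± 7.38 against 380.0 ± 18.5 TPM, Pmel, which encodes gp100, at 3172 ± 120 against 6612 ± 342, and Tyrp1 at 2011 ± 40.8 against 4985 ± 538, each lower on both scales. Of 7 tested cholinergic and anchoring genes 1, Colq itself, rose and 5 fell (adjusted p = 0.95), against 2 and 3 after size factors and 2 and 1 with the length trend removed. The median was -0.63, -0.30 and 0.15 in turn. The lower genes as deposited included Hspg2 (-1.91), and Agrn (-1.01) and Lrp4 (-0.85), the latter 2 of the neuromuscular synapse. With the length trend removed Hspg2 stayed lower (-0.75, adjusted p = 0.00074), while Agrn stood at -0.043 (adjusted p = 0.84) and Lrp4 at 0.15 (adjusted p = 0.49).

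**Figure D3:**
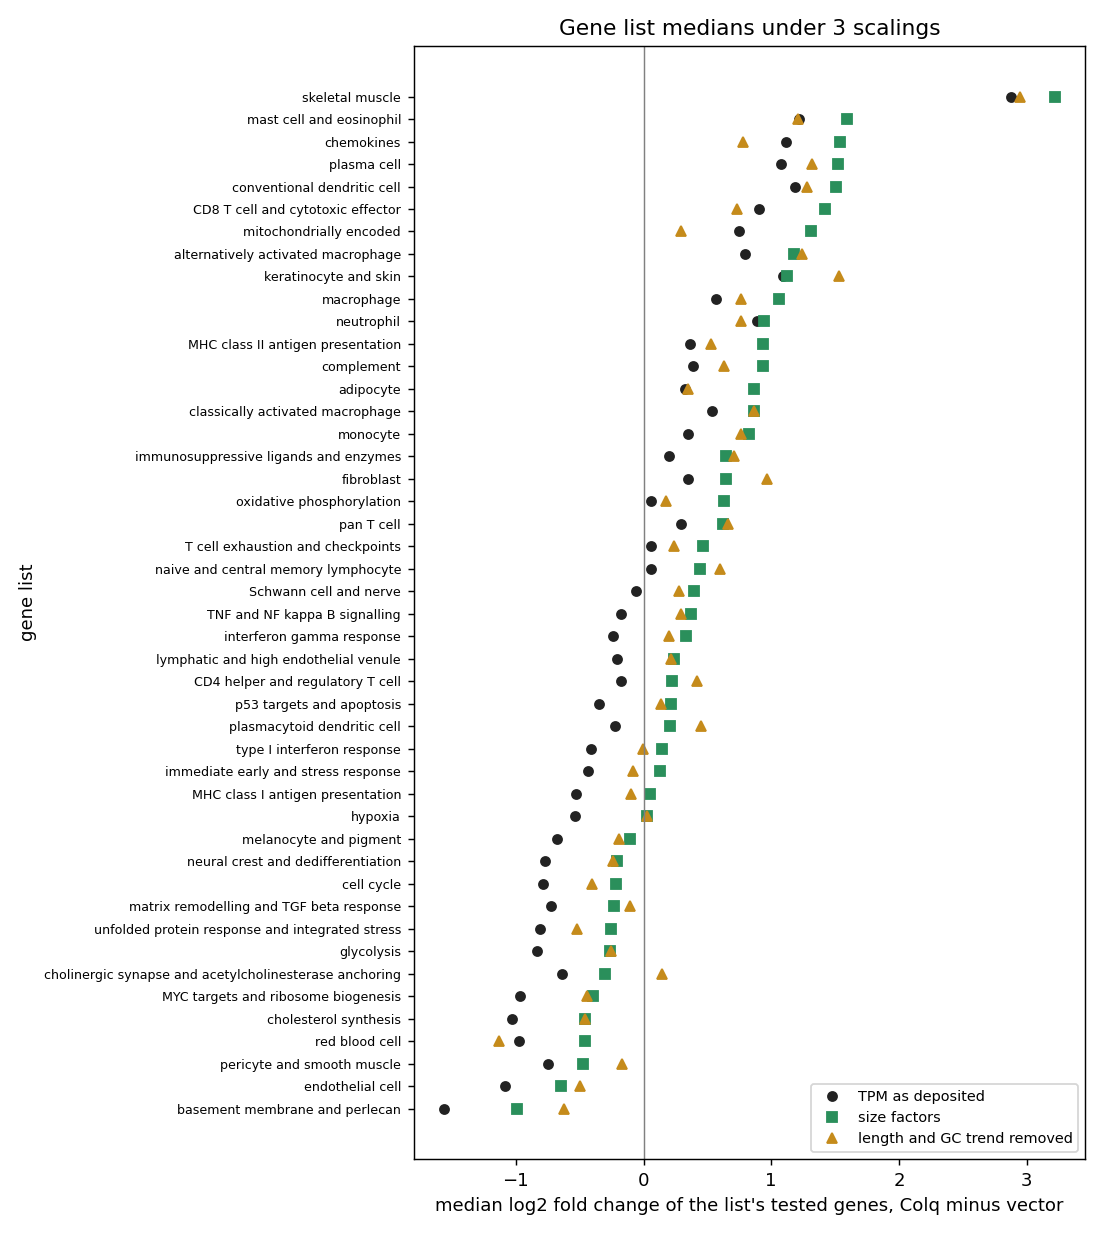
Median log2 fold change, Colq minus vector (horizontal axis), of the tested genes of each of 46 lists (vertical axis, ordered by the size factor values), as deposited (circles), after size factors (squares) and with the length and GC trend removed (triangles). Skeletal muscle is highest on each of the 3 scales, at 2.88, 3.22 and 2.95.

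Receptor repertoire measures were compared as the authors' deposited values, which are not scaled to depth. Per the entropy values, clones are counts summed over clonotypes, so the clonotypes give the number of distinct receptors. Colq tumors held 50 ± 8 TRB clones against 10.3 ± 3.06 in vector tumors, 76.7 ± 12.9 against 3 ± 2.65 IGH clones, and 165.3 ± 17.5 against 6.33 ± 3.21 IGL clones (SD, n = 3 each). TRB clonotypes numbered 21.7 ± 4.04 against 8.67 ± 2.08, IGH clonotypes 21.3 ± 3.79 against 2.33 ± 1.89 and IGL clonotypes 35 ± 3.61 against 3.33 ± 2.31. TRA clones did not separate the groups, at 21.3 ± 7.64 against 15.3 ± 8.89 (exact permutation p = 0.4), and TRA clonotypes averaged 11 in both. TRB clonality was 0.180 ± 0.027 against 0.0208 ± 0.018, on 42 to 58 clones per Colq library and 7 to 17 per vector library. In Vector replicate 3 the 7 TRB clones were 7 clonotypes, which sets clonality to 0. IGH clonality separated the groups too, at 0.256 against 0.0079. Clonality did not separate them for TRA (0.136 against 0.032, exact permutation p = 0.4) or IGL (0.190 against 0.158, exact permutation p = 0.6). IgM made up 0.977 ± 0.041 of IGH clones against 0.167 ± 0.29, a share that rests on 1 to 9 clones per vector library. Of 20 measures 12 separated the groups (exact two-sided permutation p = 0.1, the smallest possible, and adjusted p = 0.17). Among these, IGH entropy and IGH clonality had values in only 2 vector tumors, and measures of the same chain overlap. In all 0 measures passed an adjusted p of 0.05 and 0 had an unadjusted p under 0.05, which neither 3 against 3 nor 3 against 2 can reach.

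**Figure D4:**
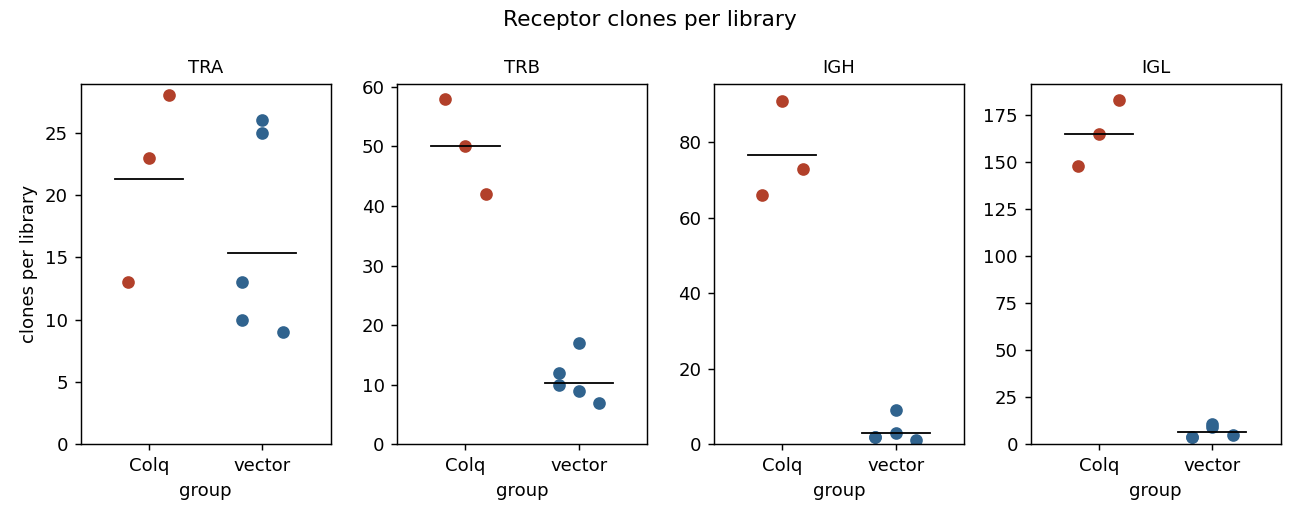
Clones per library, as counts summed over clonotypes (vertical axes, from 0), of 4 receptor chains in Colq and vector tumors (horizontal axes). Points are libraries, with portions of a tumor above one another, and lines are means over tumors, at 50 against 10.3 for TRB and 165.3 against 6.33 for IGL.

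The authors' deposited table of their own comparison held 27664 genes, of which 3850 were higher and 3904 lower in Colq tumors at its adjusted p under 0.05. Its smallest adjusted p-values belonged to Ccl6 (authors' log2 fold change 3.80), Dpt (4.79), Plac8 (3.49), Retnla (6.18) and Ckm (4.20) on the higher side, and to Fat1 (-1.77), Polr2a (-1.56), Prpf8 (-1.59), Col4a1 (-1.86) and Dync1h1 (-1.36) on the lower side. Colq stood at 5.48 in the authors' deposited table, and its sign gave the direction of that table. Across 13166 genes in both tables, which are not independent replicates, fold changes correlated at r = 0.930 and rho = 0.975, and the median difference, values computed here minus the authors', was -0.52. Both called 5168 genes in the same direction and 284 in opposite directions, and after size factors 6575 and 0.

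Portions of a tumor were set beside separate tumors. The median absolute log2 difference between portions was 0.144 in one vector tumor and 0.219 in the other, and between libraries of different vector tumors it ran from 0.148 to 0.225. Libraries of different Colq tumors differed by 0.106 to 0.111, less than either pair of portions, and Colq and vector libraries by 0.518 to 0.719. The labels name separate tumors within each group. The p-values measure the spread between these samples, which for the Colq libraries was below that between portions of 1 tumor.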

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

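The alternatives on length and GC content, on the Colq libraries as 1 sample and on genes of at least 2000 bases were chosen after the data were seen. The numbers of genes moved with the scale: size factors gave 3843 higher and 3505 lower, quantile normalization 3150 and 4243, removal of the length and GC trend 2930 and 3090, genes of at least 2000 bases with size factors 2946 and 2789, and the authors' own comparison, as deposited, 3850 higher and 3904 lower. Size factors center the median gene by construction; beyond that the cause was not tested. Counting the Colq libraries as 1 sample gave 788 higher and 5712 lower, of which 763 and 5707 were also called on 3 tumors; the vector tumors alone supply its spread. Leaving out each tumor gave 1310 to 1549 higher and 7484 to 8216 lower. The lists past the threshold numbered 13 among genes of at least 2000 bases, where fewer genes were tested. By camera with an estimated correlation 0 passed, where 7 had an unadjusted p under 0.05. By fry 30 passed, a test against 0 that takes in the shift of all genes. Same-numbered Colq and vector tumors deviated together by correlations of 0.030, 0.007 and 0.044, and differently numbered tumors by -0.054 to 0.021. These values are small, but with 3 tumors per group they cannot exclude a pairing by number. With the replicate block 1526 genes were higher, 7928 lower and 27 lists passed, and Colq stood at 2.24. Colq kept its direction and its call in every alternative in which it was tested, between 2.15 and 4.44; it falls under a mean TPM of 5. Of 3559 combinations of 159 other named genes with 23 settings, 3456 kept direction and side of the threshold, 62 lost the call, 18 gained it and 23 changed sign. The last were, after size factors, Xbp1 (0.075), Cxcl10 (0.14), Ifi30 (0.10), Bcl6 (0.10), Bst2 (0.43) and Irf9 (0.14); with quantile normalization Irf9 (0.077); with the length and GC trend removed Ikzf2 (0.32), Bcl6 (0.42), Irf9 (0.23) and Lrp4 (0.15); among genes of at least 2000 bases Xbp1 (0.17), Cxcl10 (0.24), Bcl6 (0.17) and Irf9 (0.23); and, for a gene far from the threshold, the log2 fold change Cd22 showed with all libraries as independent (-0.024), with tumor as a random block (-0.028) and with second portions (-0.013). Without single tumors Cd22 ran from -0.21 to 0.20 and Cd79b from -0.073 to 0.45. The cause of these changes was not tested. With all 8 libraries as independent, which counts portions as tumors, 8 receptor measures passed (adjusted p = 0.045); IGL clonality changed sign with first portions (-0.012). Depth is unknown and limits low genes most.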

Other observations

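Several lists outside those described above did not pass by camera on deposited TPM: TNF and NF kappa B signalling (6 higher and 9 lower of 21, adjusted p = 0.069), adipocyte (2 and 3 of 9, 0.078), lymphatic and high endothelial venule (1 and 3 of 6, 0.24), Schwann cell and nerve (2 and 5 of 11, 0.29), neural crest and dedifferentiation (2 and 10 of 15, 0.51), hypoxia (2 and 15 of 21, 0.64), matrix remodelling (4 and 18 of 29, 0.68), p53 targets (3 and 13 of 22, 0.69), pericyte and smooth muscle (1 and 10 of 15, 0.69), immediate early genes (0 and 11 of 21, 0.73) and red blood cell (0 and 2 of 6, 0.95; 0 and 6 without Vector replicate 3). Over all 13726 tested genes 1556 rose and 8181 fell on that scale. A majority of lower members therefore does not by itself set a list apart. Adjusted over the list alone, counts differed for the lymphatic list (2 and 3) and the red blood cell list (0 and 0 by limma). The medians of the TNF, lymphatic, Schwann cell, hypoxia, p53 and immediate early lists were negative as deposited and positive after size factors. Higher and lower members then numbered 10 and 4 for TNF, 3 and 1 for lymphatic, 5 and 1 for Schwann cell, 6 and 4 for hypoxia, 10 and 1 for p53 targets and 8 and 4 for immediate early genes, against 2 and 7 for neural crest, 5 and 11 for matrix remodelling, 2 and 6 for pericyte, 5 and 2 for adipocyte and 1 and 0 for red blood cell. TNF and NF kappa B signalling passed with the length trend removed (adjusted p = 0.041), with second portions (0.031), without mitochondrial, immunoglobulin and haemoglobin genes (0.047; median 0.016), without Vector replicate 1 (0.047) and without Vector replicate 2 (0.047). The adipocyte list passed without Vector replicate 1 (0.047) and without Vector replicate 2 (0.045), and with no filter the hypoxia (0.043) and matrix remodelling (0.035) lists passed toward lower.

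All tests in the paragraphs that follow were chosen after the results were seen. The labels give no library batch, so a difference in handling between the groups was not tested. The 10 splits of the 6 tumors are too few for a share under 0.05. The real split gave 1556 higher and 8181 lower genes, as many as 1 of the 10 splits in each direction, and the highest other split gave 0 by limma at an adjusted p under 0.05. Every other split mixes Colq and vector tumors in both of its groups, which widens the spread within them. Few calls would follow there whatever the cause of the difference, so no conclusion is drawn from the 0. For gene lists 3 of the 10 splits gave 27 or more, with 28 in the highest other split.

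The first pattern is the excess of lower genes, which is greater among longer genes. A larger share of TPM in ribosomal protein and mitochondrial genes is not the whole cause, since the median log2 fold change stayed at -0.30 without them, against -0.50 with them. A candidate explanation is a transcript length bias, as may arise from RNA quality or library preparation. Log2 fold change fell with length in 91.9% of the 37 lists with at least 10 genes, so the trend also runs within gene groups. The lists hold the same genes that prompted this test, so it cannot tell a technical bias from another cause of the trend. Of the 2 pairs of portions 1 differed along length, with a rank correlation across genes of 0.39 in size, and the other hardly, with 0.035, against 0.43 to 0.54 between Colq and vector libraries. An effect of Colq over-expression on long genes stays open and was not tested.

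The second pattern is that 3 separately labelled Colq tumors agreed more closely than portions of 1 vector tumor. Lower depth of the vector libraries is argued against, because among the 652 genes at a mean TPM of at least 200 the portions still differed 2.35 times as much as the Colq libraries. That ratio averages both pairs of portions, of which 1 differed along length (rank correlation 0.39 in size), which may enlarge it. Over all tested genes the closer pair, at 0.144, still differed more than the Colq libraries, at up to 0.111. A hypothesis is that the Colq libraries may come from 1 pool of tissue or RNA: 45 genes of muscle, skin and fat, which depend on how a tumor is cut out, spread between Colq libraries by 0.885 times the spread of other genes of like level, against 2.39 times between vector tumors. Of 142 variable segments of receptor chains, 8 stood at a TPM of at least 1 in all 3 Colq libraries, and 5 of these at 0 in every vector library. By the same bound 0 segments were in all vector libraries, 42 in at least 1 Colq library and 28 in at least 1 vector library. Such sharing goes with 1 pool. The vector libraries, with few receptor clones, are a poor measure of how far separate tumors share segments, so more uniform tumors in the Colq group stay open.

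The third pattern is the rise of skeletal muscle and leukocyte genes. A lower share of melanoma cells, made up by all other cell types alike, would raise endothelial genes too. After size factors these had a median of -0.64, while muscle genes had 3.22 and CD8 T cell genes 1.42, which argues against that form. A lower share made up by muscle or leukocytes alone is not excluded, since endothelial genes need not rise then. Of 23 melanocyte and pigment genes 9 fell and 7 rose after size factors (median -0.11), with Sox10 at -0.75 and Tyrp1 at -0.73. Length is not the whole cause, since with its trend removed the medians were 2.95 for muscle and 0.73 for CD8 T cell genes. Muscle taken along with the tumor, immune infiltration after Colq over-expression, or both may contribute, and neither was tested.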
